A study of Homo sapiens with 12 samples.

How the data were processed

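Small RNA was sequenced from MV3 cells, an established human melanoma line, 4 days after transfection with an empty pcDNA3 plasmid or with the same plasmid carrying wild-type MCPIP1 or the D141N point mutant. Per the labels, cells were plated at 10500 per cm2 and received 3 µg of plasmid per well with polyethylenimine for 6 h. G418 at 900 µg/ml was added 24 h after transfection. Libraries were made from 10 µg of total RNA with an Ion Total RNA-Seq kit and read on an Ion Torrent Proton. The series' design text calls the 4 libraries of a group biological replicates and says nothing more of how the cultures were separated.

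The authors deposited a table of read counts with 2792 entries, each a precursor joined to a mature miRNA, in 12 columns named by barcode, and the barcode in each label tied a column to its sample. The submitters' processing notes name FastQC 0.11.5, cutadapt 2.08, Bowtie 1.2.3 and DESeq2 1.24.0; the genome build, the miRNA annotation and the counting rule for reads with several matches are not given in the sources used here. The authors also deposited 3 tables of comparisons in the form DESeq2 writes, with short lists of selected miRNAs. In these tables baseMean is a signal, the mean over samples of counts divided by size factors, per the file headers. The fold changes and their standard errors in the authors' deposited tables are on the log2 scale, and which group is the reference is not stated. The p-value and adjusted p columns of the deposited tables hold the outcome of the authors' own test, per the file headers.

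Counts of the same mature miRNA were summed over its precursors, which gave 2576 mature miRNAs, 166 of them with more than 1 precursor. Among the 49 such miRNAs tested, the counts listed under different precursors differed by a median of 7.08%, so the same reads may have been listed more than once. A further 24 tested miRNAs had counts identical to another miRNA, for example miR-423-5p and miR-3184-3p, which lie on opposite strands of the same locus; these are reported as uncertain, since the deposited counts do not tell such pairs apart. Positions were taken from GENCODE release 29 on GRCh38, in which 1848 of 1870 precursors had a miRNA gene of the same name; this build may not be the one the authors used.

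Total counts ran from 407372 to 3808292 per library, so that 3 counts, the most that a count of 0 allows, corresponded to 0.788 to 7.36 CPM, counts scaled to a common library total. Such limits cover counting error only, because PCR copies are not independent molecules. All CPM given per group or library for tested miRNAs were scaled with TMM, whose factors ran from 0.891 to 1.06, while sums over lists and over the chromosome 14 cluster used library totals. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, on the 473 miRNAs that passed filterByExpr, with all 12 libraries in 1 model and no covariate. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The common biological coefficient of variation was 24.8%. Comparisons were of wild type with empty vector, D141N with empty vector, wild type with D141N, and wild type with the mean of the other 2 groups.

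Lists of miRNAs were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 3 tested members, with camera at an estimated correlation and with fry, with and without regard to direction, beside it. The 22 lists, of which 16 could be tested, were precursors that MCPIP1 has been reported to cleave, the let-7 family, miR-17-92 and its paralogs, melanoma growth-inhibitory and growth-promoting miRNAs, p53-induced miRNAs, miRNAs tied to NF-kB and inflammation, the miR-23/27/24 clusters, the miR-15/16, miR-30 and miR-181 families, the DLK1-DIO3 cluster, miRNAs made without Drosha, miRNAs that resemble fragments of structural RNA, the melanocyte lineage, the X-linked miR-506 to miR-514 cluster, the chromosome 19 cluster, and markers of epithelium, fibroblasts, blood, endothelium and of muscle, liver and neurons together. Agreement of the 5p and 3p arms was measured over 172 precursors with 100000 permutations of the pairing. Those permutations treat precursors, not samples, as the units.

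The groups, the main test, the lists, the alternatives of the main test and the rule for naming miRNAs were fixed before the data were examined. In each of the 3 comparisons of 2 groups, the rule named every miRNA with an adjusted p under 0.05, and with none passing it took the 10 smallest unadjusted p-values, given as values. It added the authors' selected miRNAs (miR-4484 and miR-193a-5p), the 5 most abundant miRNAs, and up to 4 members of each list that passed when adjusted over the list alone. Adjustment over a list alone was not corrected over the lists, the comparisons or the fits. miR-222-5p, miR-299-5p, miR-4521, miR-155-3p, miR-192-5p and the further miRNAs that passed over a list alone with the block fell outside this rule and were chosen after their values were seen.

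The labels number the libraries 1 to 4 in each group. Deviations from the group means of libraries with the same number correlated with r from 0.185 to 0.746 between wild type and empty vector and from 0.127 to 0.750 between wild type and D141N, all above the minimum of 0.1 set for treating the numbers as pairs. The pairing rested on number 4, since without it the correlations were 0.0225 to 0.150 and -0.0987 to 0.0724. Results with the number as a block are therefore given beside those of the first test for comparisons with wild type, where they changed a call. The alternatives were DESeq2, limma-voom, other scalings and filters, fits of only the groups compared, removal of the 5 most abundant miRNAs, and removal of each library in turn; those added after seeing the data were removal of the 3 libraries numbered 4 or of the chromosome 14 cluster, and number 4 against the others as a block.

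The method was tested on simulated data drawn from the means, totals and spread of the real libraries for wild type with empty vector, with 200 of 473 miRNAs changed. Over 10 simulations it recovered 35.8% of 1.5-fold, 73.3% of 2-fold and 93.5% of 4-fold changes, with 1.99% false calls, and with the block 58.1%, 91.6% and 99.8%, with 2.90% false calls. The adjustment is stricter when few miRNAs change, and that case was not simulated. These shares therefore do not show what the real counts of passing miRNAs could have missed. The count table holds no mRNA, so the level of ZC3H12A, the gene of MCPIP1, was not analysed here and the labels could not be checked against the transfected gene.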

Results

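The series asked how MCPIP1 shapes the miRNA profile of melanoma cells. MCPIP1, encoded by ZC3H12A, is an RNase that degrades transcripts of inflammatory genes and has been reported to cleave the loop of miRNA precursors, and the D141N substitution lies in its catalytic site and abolishes the nuclease activity. MV3 cells carried an empty vector, wild-type MCPIP1 or D141N, with 4 libraries per group. In the order of their numbers, the libraries labelled empty vector held totals of 2425728, 1134559, 3808292 and 653317 counts, those labelled wild type 2160070, 1749969, 2801349 and 532022, and those labelled D141N 870880, 1332672, 407372 and 725056. Of 2576 mature miRNAs listed, 1489 had at least 1 count and 473 were abundant enough to test.

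The profile was that of a cell rich in miR-21 and miR-29. miR-21-5p, an abundant miRNA of many tumours that lies within VMP1, took 10.96% ± 1.19 of all counts (SD, n = 12). miR-29b-3p and miR-29a-3p, which repress collagen genes and DNA methyltransferases, took 8.66% ± 1.97 and 8.56% ± 1.49. miR-19b-3p of the miR-17-92 cluster took 6.79% ± 0.545 and miR-23a-3p 3.99% ± 0.244. These 5 miRNAs held 36.0% to 41.1% of each library. miR-29b-3p and miR-19b-3p have 2 precursors each, whose counts were summed and may list the same reads; with only the precursor of most counts kept for every miRNA, their shares were 5.64% and 4.43%, and miR-19b-3p ranked 6. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 15.1 to 143), so none was treated as a second deposit of another; whether they came from separate RNA was not tested.

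The strongest difference among the 12 libraries followed the numbers in the labels, not the transfected plasmid. In all 3 libraries numbered 4, the miRNA cluster of the imprinted DLK1-DIO3 region (chromosome 14, 101022066 to 101065667, in part within the noncoding hosts MEG8, MIR381HG and MEG9) was low, at 246 CPM in empty vector, 256 in wild type and 217 in D141N, against 2325 to 5403 CPM in the other 9 libraries. Of its 37 tested miRNAs, 36 were lower in number 4 than in numbers 1 to 3 with edgeR's quasi-likelihood test, at a median log2 difference of -3.60. The first principal component, with 58.3% of the variance, separated these 3 libraries from the other 9, and the second, with 10.7%, set apart D141N replicate 3, the library with the fewest counts. D141N replicate 4 also stood apart in miRNAs typical of neurons, islet or smooth muscle cells, with 258 CPM of miR-124-3p against at most 16.9 elsewhere and 229 CPM of miR-375 against at most 5.64.

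**Figure D1:**
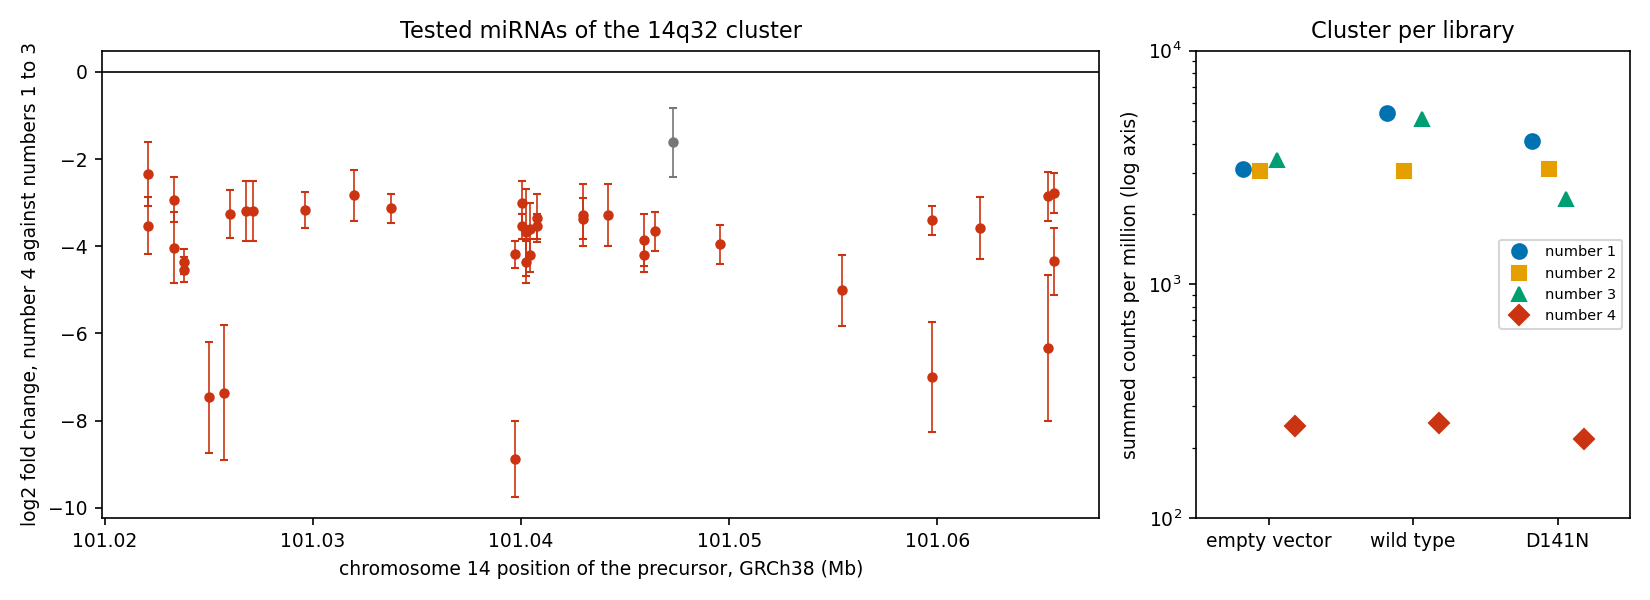
Left, log2 difference of each tested miRNA of the chromosome 14 cluster between the libraries numbered 4 and those numbered 1 to 3, by position in Mb on GRCh38, with bars of 1 standard error and red for an adjusted p under 0.05; right, summed CPM of the cluster per library on a log axis. The 3 libraries numbered 4 lie at 217 to 256 CPM and the other 9 at 2325 to 5403 CPM.

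The group names of the count table and of the authors' tables conflict. The fold changes of the authors' deposited table titled wild type and D141N had an absolute Spearman correlation of 0.425 with the labelled contrast of those groups and of 0.773 with that of D141N over empty vector, across miRNAs. The labels were kept, the groups are called by their labels, and every direction given here depends on those labels.

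The comparison of wild type with empty vector asked what the active RNase did. miR-193a-5p (MIR193A, chromosome 17, 31559996 to 31560083), from a locus described as tumour suppressive, measured 201 ± 4.38 CPM in libraries labelled wild type and 131 ± 15.8 CPM in those labelled empty vector (SD, n = 4 each), a log2 difference of 0.61 with a standard error of 0.14. Every library labelled wild type, at 196 to 206 CPM, lay above every library labelled empty vector, at 118 to 150 CPM. Its other arm, miR-193a-3p, measured 1791 ± 58.0 and 1908 ± 407 CPM. miR-222-5p (MIR222, chromosome X, 45747015 to 45747124, within the noncoding MIR222HG), the less abundant arm of a precursor that promotes melanoma growth, measured 412 ± 278 CPM in wild type and 734 ± 355 CPM in empty vector, lower in 4 of 4 pairs of the same number. The abundant arm, miR-222-3p, measured 10457 ± 901 and 10211 ± 1048 CPM.

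With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 473 miRNAs passed between wild type and empty vector, with 20 at an unadjusted p under 0.05 and 23.65 expected by chance; DESeq2 called 1, miR-193a-5p, and limma-voom 0. The adjusted p of miR-193a-5p was 0.223 with edgeR and 0.0261 with DESeq2, within 0.0261 to 0.999 over the alternatives of the unblocked fit and 0.0155 to 0.417 over the blocked settings, and 0.00518 with edgeR when adjusted over the list alone (growth-inhibitory miRNAs). With the number as a block, edgeR called 3 miRNAs, and 46 had an unadjusted p under 0.05. miR-222-5p fell by 0.93 on the log2 scale (standard error 0.14, adjusted p = 7.38e-04; 0.937 without the block, at a difference of -0.85). miR-299-5p of the chromosome 14 cluster (101023794 to 101023856) rose by 0.86 (standard error 0.17, adjusted p = 0.0181; 0.938 without the block), higher in 4 of 4 pairs, and miR-193a-5p rose by 0.61 (adjusted p = 0.0495). miR-222-5p was called in 23 of 23 blocked settings, miR-299-5p in 18 of 22, miR-210-3p (adjusted p = 0.0548 in the first of them) in 12 of 23 and miR-193a-5p in 5 of 23.

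**Figure D2:**
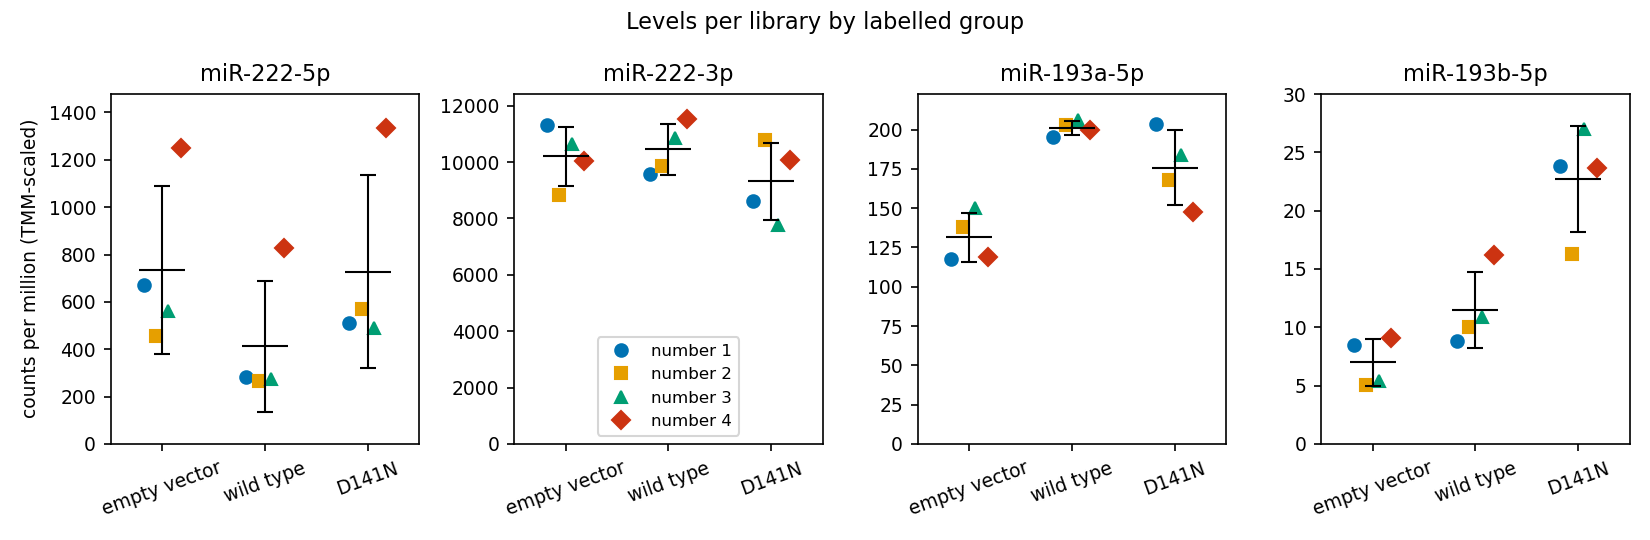
CPM of miR-222-5p, miR-222-3p, miR-193a-5p and miR-193b-5p in each library by labelled group, with colour and marker for the number and a black bar for the mean ± SD (n = 4). miR-222-5p was highest in number 4 of each group (1250, 828 and 1336 CPM) and lower in wild type than in empty vector and D141N at every number.

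The other miRNAs with the smallest p-values between wild type and empty vector did not pass, each at an adjusted p of 0.910 with edgeR without the block. miR-1246, which resembles a fragment of a small nuclear RNA, had a log2 difference of 1.14 (standard error 0.37) and miR-331-5p 0.64 (0.24). Lower values were -1.03 (0.36) for miR-30b-3p, -0.67 (0.25) for miR-4455, -0.45 (0.17) for miR-19a-5p, -0.56 (0.21) for the hypoxia-induced miR-210-3p, which passed in part of the blocked settings, and -0.69 (0.28) for miR-135b-5p. miR-423-5p and miR-3184-3p, which share their counts, had 0.33 (0.14). miR-4484, selected by the authors, measured 18.8 ± 9.79 CPM in wild type, 16.8 ± 6.06 in empty vector and 15.5 ± 8.19 in D141N (SD, n = 4 each), a difference smaller than the spread between replicates (adjusted p = 0.966 for wild type with empty vector). The 5 most abundant miRNAs differed by -0.08 for miR-29a-3p to 0.17 for miR-29b-3p (adjusted p from 0.938 to 0.968).

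Among the lists, the miRNAs made without Drosha (miR-320 family, miR-484 and short-intron miRNAs) shifted up relative to the others in wild type against empty vector. All 7 tested members had positive differences, with a median of 0.30, among them 0.93 for miR-877-3p, 0.79 for miR-320c and 0.24 for miR-484 (camera, adjusted p = 0.00703; adjusted p = 0.303 with an estimated correlation; adjusted p = 0.197 with fry). No member passed by itself or adjusted over the list alone, and the shift was lost at a mean CPM of at least 10, without empty vector replicate 1, without wild type replicate 4 and without the 3 libraries numbered 4 (adjusted p = 0.165). Of the 11 tested arms of precursors that MCPIP1 has been reported to cleave, 5 had positive and 6 negative differences with a median of -0.05, including -0.79 for miR-155-3p, 0.04 for miR-155-5p, -0.24 for miR-146a-5p, 0.30 for miR-199a-5p and -0.07 for miR-21-5p. The 31 tested members of the DLK1-DIO3 list, which is low in every library numbered 4, had 29 positive differences with a median of 0.58; with the number as a block the list shifted up (adjusted p = 0.0142; adjusted p = 0.745 with an estimated correlation). In wild type and empty vector the DLK1-DIO3 list summed to 5205 and 2972 CPM at number 1 and to 4945 and 3275 at number 3. At number 2 the sums were 2944 and 2878, and at number 4 they were 239 and 230. The rise in these sums therefore lay mainly in wild type replicates 1 and 3. With the block and adjusted over the list alone, further miRNAs passed, with no correction over the lists, the comparisons or the fits. Some lists share members, so a miRNA given under several lists is the same result. Lower in wild type were miR-155-3p (0.0336) and miR-135b-5p (0.0483) among the reported precursors, miR-155-3p (0.0199) and miR-222-5p (2.03e-05) in the NF-kB list, miR-30b-3p (0.0393) and miR-222-5p (2.81e-05) among the growth-promoting miRNAs, miR-30b-3p (0.0481) in the miR-30 family and miR-29b-1-5p (0.0325) in the growth-inhibitory list. Higher were miR-1246 (0.0216) among those resembling structural RNA, and miR-299-5p (0.00237) and miR-376c-5p (0.0372) in the DLK1-DIO3 list.

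The remaining lists did not shift between wild type and empty vector (camera, adjusted p from 0.407 to 0.984). With the block, fry called the p53-induced list (adjusted p = 0.0102; 0.833 without the block), and camera did not (adjusted p = 0.580). fry without regard to direction called the growth-inhibitory list (adjusted p = 0.0287), and with the block the growth-promoting (5.56e-05) and NF-kB lists (6.88e-04) as well. Both of the latter hold miR-222-5p, the only member of either that passed over all miRNAs with the block. Camera with the block called neither (adjusted p = 0.259 for each). In the growth-inhibitory list miR-193a-5p was the only member that passed over the list alone without the block. Medians were 0.08 for the 19 let-7 arms (12 positive), 0.04 for the 19 arms of miR-17-92 and its paralogs (14 positive), 0.09 for the 14 of miR-15/16 (9 positive), -0.03 for the 11 of miR-30 (4 positive), 0.13 for the 7 of miR-181 (5 positive) and -0.02 for the 11 of miR-23/27/24 (3 positive). The growth-inhibitory list had 6 of 11 members positive at a median of 0.08, the growth-promoting list 10 of 18 at 0.01, the p53-induced list 4 of 7 at 0.01 and the NF-kB list 8 of 13 at 0.03. The miRNAs resembling structural RNA had 1 of 7 positive at -0.16, the epithelial markers 0 of 5 at -0.18 and the fibroblast markers 5 of 5 at 0.02. The test pointed down while median and mean were positive for let-7 and miR-15/16, and for the growth-promoting and NF-kB lists the median was positive while mean and test were negative. Summed CPM of the lists too scarce to test, for empty vector, wild type and D141N, were 0, 1.61 ± 2.69 and 0.188 ± 0.375 for the melanocyte lineage, 0.755 ± 0.548, 0.473 ± 0.673 and 0.475 ± 0.572 for miR-506 to miR-514, and 0.726 ± 0.522, 0.473 ± 0.673 and 1.48 ± 1.07 for the chromosome 19 cluster (SD, n = 4). Blood markers summed to 108 ± 23.96, 105 ± 9.43 and 113 ± 7.14, endothelial markers to 188 ± 20.7, 169 ± 14.5 and 192 ± 13.4, and those of muscle, liver and neurons to 87.7 ± 14.5, 100.1 ± 17.7 and 166 ± 161, the last with 405 CPM in D141N replicate 4.

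The comparison of D141N with empty vector asked what the protein did without nuclease activity. miR-193b-5p (MIR193B, chromosome 16, 14303967 to 14304049, within the noncoding MIR193BHG), the scarce arm of a precursor described as growth inhibitory in melanoma, measured 22.7 ± 4.54 CPM in D141N and 6.98 ± 2.05 CPM in empty vector (SD, n = 4 each). The log2 difference was 1.70 with a standard error of 0.34, and wild type lay between at 11.5 ± 3.25 CPM. These CPM rest on 11 to 22 counts per D141N library and 6 to 20 per empty vector library. The abundant arm miR-193b-3p measured 593 ± 30.4 CPM in D141N and 637 ± 128 CPM in empty vector. miR-193a-5p, from the related precursor, was at 176 ± 23.8 CPM in D141N, a difference of 0.41 (standard error 0.14, adjusted p = 0.997).

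edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 miRNAs between D141N and empty vector, with 15 at an unadjusted p under 0.05, while DESeq2 and limma-voom each called 1, miR-193b-5p. Its adjusted p was 0.0627 with edgeR, 0.0265 with DESeq2 and 0.0288 with limma-voom, within 0.0265 to 0.613 over the alternatives of the unblocked fit and 0.0230 to 0.558 over the blocked settings, and 0.00146 with edgeR when adjusted over the list alone. Other named miRNAs had an adjusted p of 0.997. Among them were miR-23a-5p at a log2 difference of 0.61 (standard error 0.21), miR-877-5p at 0.64 (0.24) and miR-331-5p at 0.64 (0.25). Negative values were -1.23 (0.46) for miR-887-3p, -1.58 (0.60) for miR-3176, -0.65 (0.25) for miR-4455, -0.63 (0.25) for miR-105-3p, -1.10 (0.44) for miR-1285-5p and -0.12 (0.44) for miR-4484. Of the most abundant miRNAs, miR-29b-3p differed by -0.38 and the other 4 by -0.03 to 0.06.

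No list shifted between D141N and empty vector (camera, adjusted p from 0.184 to 0.993), and fry without regard to direction called the growth-inhibitory list (adjusted p = 1.31e-05). In that list miR-193b-5p was the only member that passed over the list alone without the block. The miRNAs made without Drosha had 6 of 7 members positive at a median of 0.21, the miR-23/27/24 clusters 9 of 11 at 0.05, and the precursors reported for MCPIP1 9 of 11 at 0.05. Signs of median, mean and test differed for the growth-inhibitory, growth-promoting, miR-17-92, miR-30 and epithelial lists. The DLK1-DIO3 members, low in number 4, had 13 of 31 positive at -0.02.

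The comparison of wild type with D141N addresses the nuclease activity, and it shares its wild-type libraries with the first comparison, so values found in both are not independent. miR-222-5p measured 412 ± 278 CPM in libraries labelled wild type and 727 ± 408 CPM in D141N, again lower in 4 of 4 pairs. miR-30b-3p, from a precursor reported to promote melanoma invasion, measured 10.8 ± 3.56 and 28.3 ± 15.5 CPM, and miR-19a-5p of the miR-17-92 cluster 52.3 ± 6.04 and 81.1 ± 13.4 CPM. miR-193b-5p had a log2 difference of -1.01 with a standard error of 0.33.

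Between wild type and D141N, edgeR's quasi-likelihood test called 0 miRNAs, with 29 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. With the number as a block, edgeR called 1 miRNA, and 48 had an unadjusted p under 0.05: miR-222-5p fell by 0.88 on the log2 scale (standard error 0.14, adjusted p = 0.00172; 0.890 without the block, at a difference of -0.84), and it was called in 23 of 23 blocked settings. When adjusted over the list alone, miR-30b-3p had an adjusted p of 0.0448 among the growth-promoting miRNAs and 0.0274 in the miR-30 family, and miR-19a-5p 0.0440 among miR-17-92 and its paralogs. With the block miR-19a-5p no longer passed (0.0740), as the difference went from -0.64 to -0.62 and its standard error from 0.18 to 0.19. With the block and adjusted over the list alone, miR-155-3p (0.0409) and miR-146a-5p (0.0498) passed among the reported precursors and in the NF-kB list (0.0242 and 0.0393), as did miR-222-5p (4.73e-05 in the NF-kB list, 6.56e-05 in the growth-promoting list) and miR-193b-5p (0.0486), all lower in wild type. miR-29b-3p (0.0244), miR-192-5p (0.0298) and miR-299-5p (0.00953) passed as higher. The 10 miRNAs with the smallest p-values each had an adjusted p of 0.543 over all miRNAs. Beside miR-193b-5p, log2 differences were -1.32 (standard error 0.37) for miR-30b-3p, -0.64 (0.18) for miR-19a-5p, -0.45 (0.15) for miR-340-5p, -1.51 (0.50) for miR-23b-5p and -0.43 (0.15) for miR-3613-5p. Positive ones were 1.31 (0.44) for miR-1285-5p, 1.60 (0.54) for miR-4443, 1.32 (0.45) for miR-362-5p and 0.71 (0.25) for miR-105-3p. miR-4484 differed by 0.34 (0.43, adjusted p = 0.928), miR-193a-5p by 0.19 (adjusted p = 0.890) and miR-29b-3p by 0.55 (0.20, adjusted p = 0.644).

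No list shifted between wild type and D141N without the block (camera, adjusted p from 0.277 to 0.982). The precursors reported for MCPIP1 had 8 of 11 arms negative at a median of -0.09, with -0.54 for miR-146a-5p, and the miR-23/27/24 clusters 10 of 11 at -0.09. For the growth-inhibitory and p53-induced lists, median, mean and test differed in sign. In wild type and D141N the DLK1-DIO3 list summed to 5205 and 3903 CPM at number 1 and to 4945 and 2197 at number 3. At number 2 the sums were 2944 and 2990, and at number 4 they were 239 and 204. With the block, the DLK1-DIO3 list, low in number 4, shifted up (adjusted p = 5.98e-05; adjusted p = 0.518 with an estimated correlation). fry without regard to direction then called the growth-promoting (adjusted p = 8.34e-06), growth-inhibitory and NF-kB (6.36e-04 each), reported precursor (0.0260) and p53-induced lists (0.0262), and none without the block. In the growth-promoting and NF-kB lists miR-222-5p was the only member that passed over all miRNAs with the block.

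Wild type was also compared with the mean of empty vector and D141N, which both lack added nuclease activity. edgeR's quasi-likelihood test called 0 miRNAs, with 27 at an unadjusted p under 0.05, as DESeq2 and limma-voom also called 0. With the block edgeR called 2: miR-222-5p fell by 0.90 (standard error 0.12, adjusted p = 2.21e-04) and miR-299-5p rose by 0.82 (adjusted p = 0.00459). Adjusted over the list alone, miR-193a-5p (0.0418), miR-30b-3p (0.0399 and 0.0244) and miR-19a-5p (0.0493) passed. The lists gave adjusted p-values of 0.229 or more, and with the block the DLK1-DIO3 list shifted up (adjusted p = 2.12e-04; adjusted p = 0.507 with an estimated correlation). With the block and adjusted over the list alone, miR-155-3p (0.0128 and 0.00755), miR-135b-5p (0.0314), miR-222-5p (8.40e-06 and 6.07e-06) and miR-29b-1-5p (0.0380) also passed as lower. miR-25-3p (0.0435), miR-192-5p (0.0225), miR-192-3p (0.0404) and 8 DLK1-DIO3 members (6.02e-04 to 0.0494) passed as higher. fry without regard to direction called 0 lists, and with the block the reported precursor, miR-17-92, growth-inhibitory, growth-promoting, p53-induced and NF-kB lists (adjusted p from 2.03e-06 to 0.00794). Here too miR-222-5p was the only growth-promoting or NF-kB member that passed over all miRNAs with the block.

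A change in a precursor moves both of its arms, so the log2 differences of 5p and 3p arms were compared across 172 precursors, which are not independent replicates. The arms of miR-3130 had identical counts and so agreed by construction. The arms of miR-214 and miR-3120 shared counts, as did those of miR-338 and miR-3065. None of these pairs was left out, and the permutations treated them as separate. The arms moved together between wild type and empty vector (Pearson r = 0.329, permutation p = 2e-05, adjusted p = 6e-05; Spearman rho = 0.252). Without the chromosome 14 cluster r was 0.166 (permutation p = 0.0380), without empty vector replicate 4 it was 0.121 (permutation p = 0.108) and without wild type replicate 1 0.122 (permutation p = 0.104). Between D141N and empty vector r was -0.0243 (permutation p = 0.750; rho = 0.0141). Between wild type and D141N r was 0.183 (permutation p = 0.0176, adjusted p = 0.0265; rho = 0.158), and it was 0.0295 without the chromosome 14 cluster and 0.115 with the block (permutation p = 0.133).

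The authors' deposited table titled wild type and empty vector listed miR-193a-5p at a log2 fold change of -0.55 (standard error 0.13, adjusted p = 0.0112), the only miRNA of 785 to pass. That sign is opposite to the 0.61 fitted here, and the fold changes of that table ran opposite to labelled wild type over empty vector (Spearman rho = -0.831 across miRNAs), with the reference group not stated. The authors' deposited table titled for all 3 groups listed miR-4484 at -7.02 (standard error 1.65, adjusted p = 0.0166) among 796 miRNAs. The authors' deposited table titled wild type and D141N listed miR-4484 at -6.67 (standard error 1.62, adjusted p = 0.0277) among 716. In the count table miR-4484 had 30, 26, 82 and 7 counts in empty vector, 39, 37, 77 and 3 in wild type and 18, 13, 3 and 19 in D141N, and no fitted difference of that size. The 3 tables named 105, 106 and 86 miRNAs that the count table did not.

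**Figure D3:**
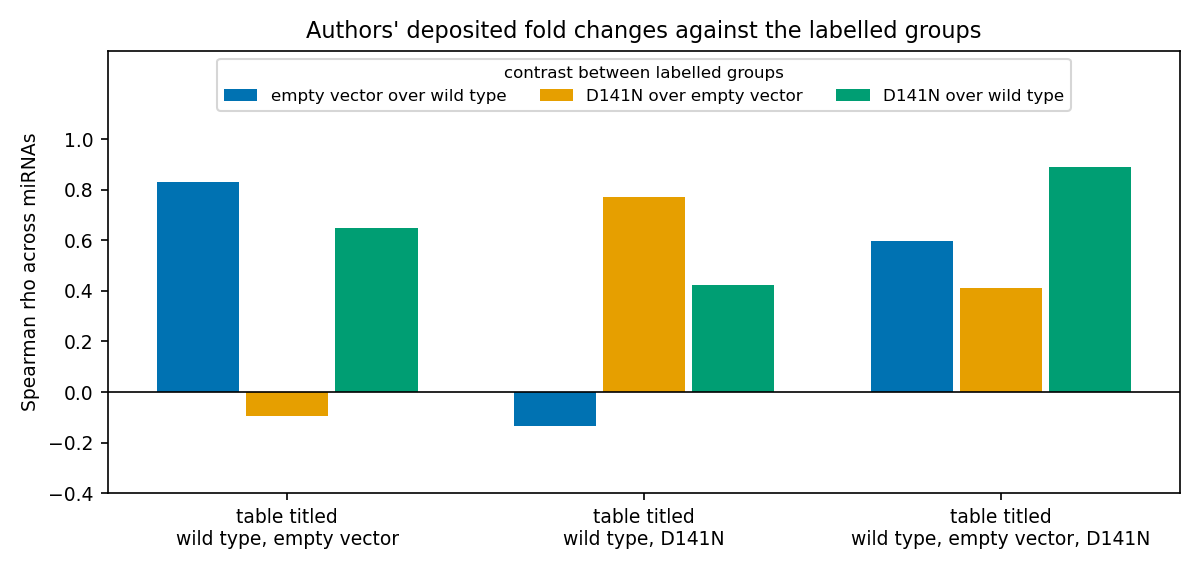
Spearman correlation of the fold changes in each of the authors' deposited tables with 3 contrasts computed from the labelled groups (empty vector over wild type, D141N over empty vector, D141N over wild type), across miRNAs. The table titled wild type and D141N reaches 0.773 with D141N over empty vector and 0.425 in absolute size with D141N over wild type.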

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

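The tests in this part were chosen after the result was seen, except that of GC content, whose bound was written before its value was computed. A library was singled out when its distance to the nearest of the other 3 libraries of its group took up most of the group's range. Chance does this in about 1 in 20 groups, and it singled out 14 groups, against 7.05 expected, 5 of them with number 4 apart.

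Number 4 stood apart in the DLK1-DIO3 list, whose members summed to 229.6 CPM in empty vector replicate 4 and to 2878 to 3275 CPM in the other 3. It also stood apart in miR-222-5p, at 828 CPM in wild type replicate 4 against 265 to 282, and at 1336 CPM in D141N replicate 4 against 489 to 569. The epithelial markers summed to 242 CPM in wild type replicate 4 against 394 to 414, and were also low in number 4 of empty vector (248 against 405 to 527) and D141N (310 against 444 to 476), and miR-23a-5p measured 77.6 CPM in D141N replicate 4 against 66.0 to 66.7.

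The first of these values belongs to a loss of the chromosome 14 cluster in all 3 libraries numbered 4, and the others lie outside the cluster and were not explained. Between number 4 and numbers 1 to 3, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 16 miRNAs higher and 48 lower, 16 and 12 of them outside the cluster. Of the 64 ways to pick 1 library per group, the real pick gave 64 calls and the highest other 4, 1 of 64 having as many; the pick could have been any of the 4 numbers, so the splits are too few for a share under 0.05. Depth is argued against, since the median of the cluster stayed at -3.52 after every library was thinned to 407372 counts. A bias by GC content of the precursor is also argued against, since 91 other miRNAs of matching precursor GC content had a median of -0.0186. The GC content of the sequenced mature miRNAs was not computed, so a bias by it is left open. Replacement by another cell type is argued against as well, since 1.83% of the 436 tested miRNAs outside the cluster changed by 2-fold or more with an adjusted p under 0.05 (8 miRNAs). This does not cover a smaller share of admixed cells, since miR-200a-3p (log2 difference -1.06), miR-200b-3p (-0.64) and miR-429 (-0.88), epithelial markers of 1 locus on chromosome 1, were also called lower. Another epithelial marker, miR-200c-3p, was not lower in number 4, so these markers did not all move together. A different stock, passage or clone of MV3 cells with an altered imprinted region, shared by the cultures numbered 4, may remain among the explanations and was not tested, and the labels give no date or batch.

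Other libraries stood apart in the following. miR-362-5p measured 14.3 CPM in empty vector replicate 1 against 9.05 to 9.68 in the others. The miR-15/16 family summed to 69380 CPM in empty vector replicate 1 against 54149 to 54998. In empty vector replicate 3 the miR-23/27/24 clusters summed to 93126 CPM against 81968 to 83512, and the miRNAs made without Drosha to 3306 CPM against 2806 to 2853. miR-23a-5p measured 59.7 CPM in wild type replicate 3 against 50.1 to 50.5. Wild type replicate 2 had miR-29a-3p at 43664 CPM against 93097 or more in the others, the growth-promoting list at 171754 CPM against 141421 to 144896, and the NF-kB list at 163116 CPM against 134263 to 136961. The growth-promoting list also summed to 167447 CPM in D141N replicate 2 against 157998 to 159108. Both lists hold miR-21-5p, which took 10.96% of all counts and makes up most of their sums, so these sums are not separate results.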

How the results depend on the processing

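Counts of passing miRNAs from edgeR moved little with scaling but with the tool, the filter, the replicate block and the libraries numbered 4; where a library or miRNA is not named as the reason, the cause was not tested. The alternatives without number 4, without the chromosome 14 cluster, with number 4 against the others as a block, and all blocked settings beyond the first were chosen after seeing the data. For wild type with empty vector the count of 0 became 1 with DESeq2, 3 with the replicate block, 4 without the 3 libraries numbered 4 and 3 with number 4 against the others as replicate block; without each library in turn it was 0 to 1, the 1 being miR-4521 without wild type replicate 4. For D141N with empty vector, 0 became 1 with DESeq2, limma-voom, an adjusted p under 0.1, number 4 against the others as replicate block, and without the chromosome 14 cluster, and 2 with no filter on low counts (miR-335-5p and miR-708-5p, named after their values were seen). For wild type with D141N, 0 became 1 with the replicate block, without number 4 and with number 4 against the others as replicate block; for wild type with the mean of the others the 3 settings gave 2, 5 and 2.

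In the blocked fit, wild type with empty vector had 3 calls and 5 with DESeq2, 5 with limma-voom, 6 with no filter and 1 to 5 without each library in turn (1 without empty vector replicate 1, wild type replicate 1 or wild type replicate 3, and 5 without D141N replicate 2). D141N with empty vector had 0 and 1 with DESeq2 or limma-voom, 6 with no filter, 2 at a mean CPM of at least 10, 1 with number 4 against the others, and 0 to 1 without each library (1 without D141N replicate 2). The 6 included miR-124-3p, miR-375 and miR-34a-5p, the 2 were miR-124-3p and miR-193b-5p, and the call without D141N replicate 2 was miR-34a-5p. miR-124-3p, miR-375 and miR-34a-5p were high in D141N replicate 4 alone (258, 229 and 169.6 CPM), so their calls may rest on that library. D141N and empty vector were not treated as pairs by number. Their same-number correlations ran from 0.0718 to 0.728, the lowest being under the minimum of 0.1, and 2 of 8 samples were closest to their own number. The sample titles give libraries of the same number a common code in all 3 groups. The low chromosome 14 cluster is also shared by all libraries numbered 4, so these groups may still be paired as the others are. Wild type with D141N had 1 and 2 with DESeq2, limma-voom, a mean CPM of at least 10 or without number 4, 12 with no filter, and 1 to 15 without each library (15 without D141N replicate 2, and 2 without wild type replicate 2 or 4). Among the 12 were miR-124-3p, miR-375 and miR-34a-5p, high in D141N replicate 4 alone. miR-124-3p was also called at a mean CPM of at least 10, and miR-34a-5p was among the 15. Wild type with the mean had 2 and 7 with DESeq2, 6 with limma-voom, 8 with no filter, 4 without number 4, and 1 to 12 without each library (12 without D141N replicate 2, 5 without empty vector replicate 4, 4 without wild type replicate 4, and 1 without wild type replicate 1 or 3).

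The 40 log2 differences followed here left out the 5 most abundant miRNAs and included miR-222-5p and miR-299-5p, which fell outside the naming rule. Of these 40, 36 kept their direction in every alternative that gave a value. Over 1066 values 1033 kept direction and side of the threshold, 16 newly passed and 17 changed sign. None could newly fail, since no miRNA passed in the main fit. miR-4484 ran from -0.0748 to 0.41 without each library for wild type with empty vector, and from -0.43 to 0.0572 for D141N with empty vector. For D141N with empty vector, miR-222-5p was at 0.00842 with limma-voom, 0.0255 with library totals and -0.49 to 0.32 without each library, and miR-299-5p at -0.41 with limma-voom, -0.0366 with upper quartile scaling, -0.0138 with no filter and -0.34 to 0.42 without each library; differences this near 0 have no direction. Low miRNAs gave no value at a mean CPM of at least 10 (miR-3176, miR-1285-5p, miR-23b-5p, miR-4443) or in fits of only the groups compared (miR-3176, miR-1285-5p, miR-4443); miR-105-3p gave none per precursor and miR-299-5p none without the cluster. Library totals alone moved the median of all miRNAs by -0.04, 0.03 and -0.07 in the 3 comparisons of 2 groups.

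Of the lists, 1 passed for wild type with empty vector, 0 with an estimated correlation, fry or a mean CPM of at least 10, 2 with the replicate block, 3 without number 4 and 0 to 1 without each library (0 without empty vector replicate 1). For D141N with empty vector 0 passed and 0 to 1 without each library (the DLK1-DIO3 list without empty vector replicate 4). For wild type with D141N 0 passed, 1 with the replicate block, 2 without number 4 and 0 to 1 without each library (the DLK1-DIO3 list without wild type replicate 4 or D141N replicate 1), and for the mean 0, 1, 4 and 0 to 3 (1 without wild type replicate 1, 3 without wild type replicate 4). Arm agreement ran from 0.121 to 0.432 without each library for wild type with empty vector and from -0.0453 to 0.143 for D141N with empty vector. For wild type with D141N it was 0.115 with the replicate block, 0.0295 without the chromosome 14 cluster, 0.108 without number 4 and -0.0235 to 0.338 without each library (lowest without D141N replicate 4). Adjusted over the growth-inhibitory list alone, 1 call for D141N with empty vector became 3 with the replicate block, with miR-193a-5p and miR-29b-3p added. Except for the calls named here and in the comparisons, the replicate block changed no other call.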

Other observations

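The tests in this part were chosen after the result was seen, except the counts over other splits of the samples and the test of the less abundant arms. The fits without the 3 libraries numbered 4, with 3 libraries per group, were also added after seeing the data.

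Without number 4, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4 of 525 tested miRNAs between wild type and empty vector. miR-155-3p, the scarce arm of the NF-kB target MIR155HG (chromosome 21, 25573980 to 25574044), fell by 1.14 on the log2 scale (standard error 0.24, adjusted p = 0.0142), miR-222-5p fell by 1.08 (0.15, adjusted p = 1.42e-04) and miR-4521 fell by 1.00 (adjusted p = 0.00450), while miR-299-5p rose by 0.83 (adjusted p = 0.0142). Against the mean of the other groups, miR-192-5p, a p53-induced miRNA, rose by 0.61 (adjusted p = 0.0408). The abundant arm miR-155-5p had a difference of -0.18 (adjusted p = 0.776) and miR-146a-5p, which restrains NF-kB signalling, -0.45 (adjusted p = 0.686). At number 4, left out here, miR-155-3p had 28 of 532022 counts in wild type and 31 of 653317 in empty vector. Relative to these totals it was not lower in wild type, nor were miR-155-5p (1759 and 1548 counts) and miR-146a-5p (657 and 688).

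Several lists passed in the same fit with camera at its preset correlation, and none with an estimated one. Of the 11 tested arms of precursors reported to be cleaved by MCPIP1, 9 were lower in wild type than in empty vector, with a median of -0.10, and the list shifted down (adjusted p = 0.0364; adjusted p = 0.227 with an estimated correlation). Against D141N the list also had 9 of 11 lower (adjusted p = 0.0404; adjusted p = 0.409 with an estimated correlation), with the same wild-type libraries in both. The NF-kB list, which shares miR-155, miR-146a and miR-21 with it, had 8 of 13 lower against empty vector (adjusted p = 0.0364; adjusted p = 0.227 with an estimated correlation), and the miR-30 family shifted down against the mean of the others (adjusted p = 0.0448; adjusted p = 0.295 with an estimated correlation). The DLK1-DIO3 list had 31 of 35 members higher than in empty vector (adjusted p = 3.55e-06; adjusted p = 0.454 with an estimated correlation). Its summed CPM was raised mainly in wild type replicates 1 and 3. With all 12 libraries and no block only the Drosha-independent list passed, and with the block the DLK1-DIO3 list passed as well, so the shifts of the other lists named here appeared only with number 4 left out or, against the mean for the reported precursors and miR-30, wild type replicate 4 alone.

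The libraries behind the authors' deposited tables, by their levels and the contrast followed, match the titles as labelled for 2 of 3 tables. The authors' deposited table titled wild type and D141N matched the mean levels of the libraries labelled empty vector and D141N (median absolute log2 deviation of baseMean 0.0440) more closely than those labelled wild type and D141N (0.0968). The signs ran against labelled wild type over empty vector in the table titled for these groups (rho = -0.831) and against labelled wild type over D141N in the table titled for all 3 (rho = -0.892). A mere change of reference group is argued against, since the absolute correlation with the contrast of its title was 0.425, below 0.773 for another. An exchange of the names empty vector and wild type between labels and tables, after which 3 of 3 tables match their titles in libraries and in a common direction of the fold changes, and a wrong title on 1 table, with the labels right, cannot be told apart, because both leave the same fold changes, the reference group is not stated and no transfected gene was measured. The tables as labelled also share a direction, with rho = 0.831 for empty vector over wild type, 0.773 for D141N over empty vector and 0.892 for D141N over wild type. The common direction therefore does not favour the exchange. If the names were exchanged, every direction given here between wild type and empty vector would turn, and the comparison of wild type with D141N would be that of empty vector with D141N.

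D141N replicate 4 held 5 miRNAs far above every other library, namely miR-124-3p at 258 CPM, miR-375 at 229, miR-34a-5p at 169.6, miR-145-5p at 77.2 and miR-143-3p at 56.5, the lowest of the ratios to the highest other library being 12.9. Spill-over from another library of the series is argued against by that ratio of 12.9. RNA from fibroblasts or smooth muscle cannot be told apart from a change in the cells, since the miR-199 and miR-214 arms, at a median ratio of 1.16 to the other libraries, had a median level of 310 CPM there, which would hide a small share. The scarcer arms had ratios of 2.91 for miR-199b-5p, on 5 counts, 1.32 for miR-214-5p and 1.17 for miR-214-3p. RNA from neural tissue may remain a source and cannot be told apart either, since 15 detected neural miRNAs of 17 listed had a median ratio of 1.75, and miR-7-5p, miR-128-3p and miR-137, abundant in MV3 cells themselves, would hide a small share. Neural miRNAs scarcer elsewhere went with such a source, with ratios of 9.28 for miR-135a-5p, 4.81 for miR-153-3p, 4.79 for miR-129-5p, 3.88 for miR-139-5p and 3.47 for miR-129-2-3p on 6 to 161 counts, while miR-9-3p (1.238) and miR-212-3p (0.874) did not. The marker ratios, unlike that of 12.9, had a small constant added to both levels. For miR-135a-5p, at 8.28 CPM against a median of 0 elsewhere, the size of the ratio rests on that constant. No biological explanation was tested, since the other 3 D141N libraries did not share the pattern.

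A hypothesis was that the nuclease lowers the whole miR-222 precursor. The log2 ratio of miR-222-5p to miR-222-3p averaged -4.85 in wild type, -3.90 in empty vector and -3.80 in D141N, with miR-222-5p chosen for being low in wild type. Within numbers, miR-222-3p differed from the mean of the others by 0.11 (standard error 0.0711) and miR-222-5p by -0.89. A lower precursor would move both arms once each has turned over, so it is argued against as far as miR-222-3p turns over within 4 days, which was not tested. An arm-specific effect may be a candidate explanation, found and tested on the same data. A wider hypothesis, that less abundant arms in general fall relative to abundant ones, was negative, with a mean difference of -0.00201 over 172 precursors (2-sided exact permutation within numbers over 81 arrangements, p = 0.963).

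The unblocked counts were 0, which every split of the samples reaches, so their splits say nothing about chance. These were 35 of 35 splits for wild type with empty vector (highest other 1), for D141N with empty vector (highest other 0) and for wild type with D141N (highest other 2), and 100 of 100 drawn splits for wild type with the mean. The highest of the drawn splits had 36 calls and put the 3 libraries numbered 4 with D141N replicate 3, which points to the structure of the samples. For the blocked counts, the real split gave 3 calls for wild type with empty vector and the highest other 0, and 1 for wild type with D141N and the highest other 0, with 1 of 8 splits within numbers as large in each, too few for a share under 0.05. For wild type with the mean, 4 of 81 splits within numbers gave 2 calls or more, the highest other having 4. That share lies close to 0.05 and was not adjusted over the blocked counts tested, so chance is not excluded.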
